A study of Mus musculus with 6 samples.

How the data were processed

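The data are 10x Genomics 3' single-cell RNA sequencing libraries of mouse placenta, 1 library per dam and 3 dams per group. Per the labels, dams carrying Tie2-GFP and KDR-mCherry reporters breathed filtered air or 1 ppm ozone for 4 h on gestational day 10, and 7 placentas per dam were pooled on gestational day 18 after excess decidua was removed. The deposited counts are UMIs per gene and barcode, which the authors made with bcl2fastq 2.20.0.422 and Cell Ranger on mm10 with the reporter sequences added. The submitters' processing notes give Cell Ranger 3.1.1 and the matrix headers 3.1.0. The matrices hold 21861 features, 50 of which share their symbol with another, and lack long non-coding RNA genes such as Xist. A deposited table by the authors lists 46587 of the 58936 barcodes with their library, exposure, processing round and 1 of 17 cell type labels. How cells were filtered, clustered and named is not stated. Of the 12349 barcodes outside the table, 7776 had a higher mitochondrial share than any kept cell of their library, and the rest were left out for reasons that the files do not give. Only the barcodes in the table were used for the comparisons. The labels DS, HBC, FM and AngioEndo are used as given because no source spells them out.

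Barcodes per library were 15612, 6893 and 8574 in filtered air 1 to 3 and 4856, 14712 and 8289 in ozone 1 to 3. Kept cells were 12968, 5940 and 7253 in filtered air and 3195, 10695 and 6536 in ozone libraries. Total UMIs were 61515239, 58935419, 63122624, 38363226, 93272607 and 75295832 in the same order. Dams, not cells, are the replicates, so tests compare 3 filtered air libraries with 3 ozone ones, except 3 with 2 in Erythrocytes and 2 with 2 in NK Cells, where the other libraries had too few cells.

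UMIs of the kept cells were summed per library over all cells, over endothelial cells (Endothelial and AngioEndo), over pericytes and over each other cell type. A library entered a cell type with at least 20 cells, and a type was tested with at least 2 libraries per group, which left out Basophils and AngioEndo on its own. Sums were tested with the quasi-likelihood method of edgeR 4.0.16 in R 4.3.3, with TMM normalization, filterByExpr and Benjamini-Hochberg adjustment at 0.05. Levels are given as CPM, and log2 CPM values use a prior count of 2. The interaction of cell class and exposure was tested on 2 sums per library, with library as a block. Shares of kept cells were compared by two-sided exact permutation tests. The 61 gene lists (38 pathway and 23 marker lists) were tested with camera of limma 3.58.1 on voom values, with a preset correlation of 0.01, at least 4 tested members and adjustment over the lists of a cell type. Gene positions were matched by gene ID to GENCODE M21.

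The comparisons, tests, gene lists, most alternative settings and the rule for naming genes were fixed before the data were examined. By that rule the text names, for all cells, endothelial cells and pericytes, the genes past an adjusted p of 0.05 with the 3 ozone sums on one side and a mean log2 CPM of at least 3, up to the 12 highest and 12 lowest and up to 4 per list. Where fewer than 10 passed, it names the 10 of smallest p and says that they do not pass. For each other type it allows the 3 highest and 3 lowest among genes that pass, and none did. List members named beside a list's median, and the genes named in other cell types, were chosen after their values were seen.

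Tested on simulated data made from these libraries, the gene test recovered 7.2% of 2-fold and 68.6% of 4-fold changes over all cells, 6.4% and 69.8% in endothelial cells and 10.6% and 76.4% in pericytes. Of the genes it called there, 9.11%, 10.1% and 7.25% were unchanged ones. Each gene was simulated independently and without a difference between rounds, so recovery in the real libraries may differ. Camera with the preset correlation called a shifted list in 5 of 5 runs for each, with 3, 0 and 3 calls among unshifted lists. With an estimated correlation it called the shifted list in 0 of 5. Genes of a list were simulated as independent, so these runs do not show how often the preset calls falsely where list members are correlated. In the real libraries, other splits into 3 and 3 put 11 to 35 lists past the preset test over all cells.

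The alternatives fixed in advance were RLE size factors, DESeq2 1.42.0, no filter on low counts, leaving out each library, a replicate block, leaving out hemoglobin and mitochondrially encoded genes, equal numbers of cells (3195 for all cells, 239 for endothelial cells and 198 for pericytes, or 100 for other types), a hemoglobin covariate, an estimated correlation and fry for lists, and shares without Erythrocytes. Alternatives chosen after the data were seen were the processing round as a covariate, cells with at least 2500 UMIs, leaving out the 2694 cells with the highest doublet scores (at least 5% of each library, ties included), the legacy quasi-likelihood fit and the label Endothelial alone. Scrublet, run through scanpy 1.11.5 with Python 3.11.15, marked 1 of 46587 cells as a doublet. Leaving out 1 cell would change nothing, so the run without doublets was not made. Whether the authors had removed doublets beforehand is not stated.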

Results

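Gestational ozone inhalation was studied in mice by single-cell RNA sequencing of the placenta, and the title of the series directs attention to placental pericytes and endothelial cells. Pregnant dams breathed 1 ppm ozone, an oxidant air pollutant, or filtered air for 4 h on gestational day 10. Placental cells were profiled 8 days afterwards, on gestational day 18, with 7 placentas pooled per dam. The 6 libraries, 3 from filtered air and 3 from ozone dams, held 46587 cells that the authors had assigned to 17 cell types. Kept cells per library ranged from 3195 in ozone 1 to 12968 in filtered air 1, and their unique molecular identifiers (UMIs) from 28134907 in ozone 1 to 76840857 in ozone 2. Median UMIs per kept cell lay between 751 and 2223.5. The deposited cell table places filtered air 1, ozone 1 and ozone 2 in a processing Round 1, and filtered air 2, filtered air 3 and ozone 3 in Round 2. Differences within each round are therefore given beside the shares and the named lists that pass in all cells, endothelial cells and pericytes, and their direction beside the genes of smallest p there.

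Which cells made up the placentas was compared first. Trophoblast 1 cells, led by the giant cell cathepsins Ctsq and Ctsj, were the largest type, with 46.4% ± 9.20 of kept cells in filtered air and 34.0% ± 1.49 in ozone libraries (SD, n = 3 each). HBC cells, a label that the sources do not spell out and that is led by Arg1, Mmp12 and Gpnmb, genes of tissue macrophages, made up 3.54% ± 0.695 of filtered air and 8.97% ± 3.07 of ozone cells. YolkSac cells, led by the endoderm genes Afp and Ttr, took 1.21% ± 0.157 and 2.85% ± 1.34, and Basophils 0.109% ± 0.0235 and 0.273% ± 0.104. For these 4 types each ozone library lay on the same side of each filtered air library. The differences within rounds, ozone minus filtered air, were 6.29 percentage points in Round 1 and 2.52 in Round 2 for HBC. They were 1.67 and 1.39 for YolkSac, 0.141 and 0.178 for Basophils, and -22.2 and -8.52 for Trophoblast 1. Among kept cells with at least 2500 UMIs, a limit chosen after the data were seen, the groups overlapped for each of the 4 types. The Trophoblast 1 difference there was -6.17 points (exact permutation p = 0.4) and its direction changed in Round 1, with 2.10 points there and -10.6 in Round 2. HBC cells took 7.85% ± 5.03 and 15.2% ± 5.37 (exact permutation p = 0.2), with filtered air 1 at 13.5% above ozone 3. YolkSac cells took 1.19% and 1.95% (exact permutation p = 0.4) and Basophils 0.418% and 0.764% (exact permutation p = 0.2). The cell types of the title differed by less than the SD of either group, with 9.05% ± 2.06 against 9.54% ± 3.09 for Endothelial cells and 7.11% ± 3.26 against 7.25% ± 2.03 for Pericytes. Within rounds the differences were 0.207 points in Round 1 and -0.209 in Round 2 for Endothelial cells, and 1.68 and 1.14 for Pericytes. Each of the 4 types reached p = 0.1 in a two-sided exact permutation test, the smallest p that 3 against 3 libraries allow in an exact test, and an adjusted p of 0.425 over the 17 types. No share could therefore pass at 0.05. edgeR's quasi-likelihood test on cell counts gave 0 types at an adjusted p below 0.05, with HBC at an adjusted p of 0.172.

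**Figure D1:**
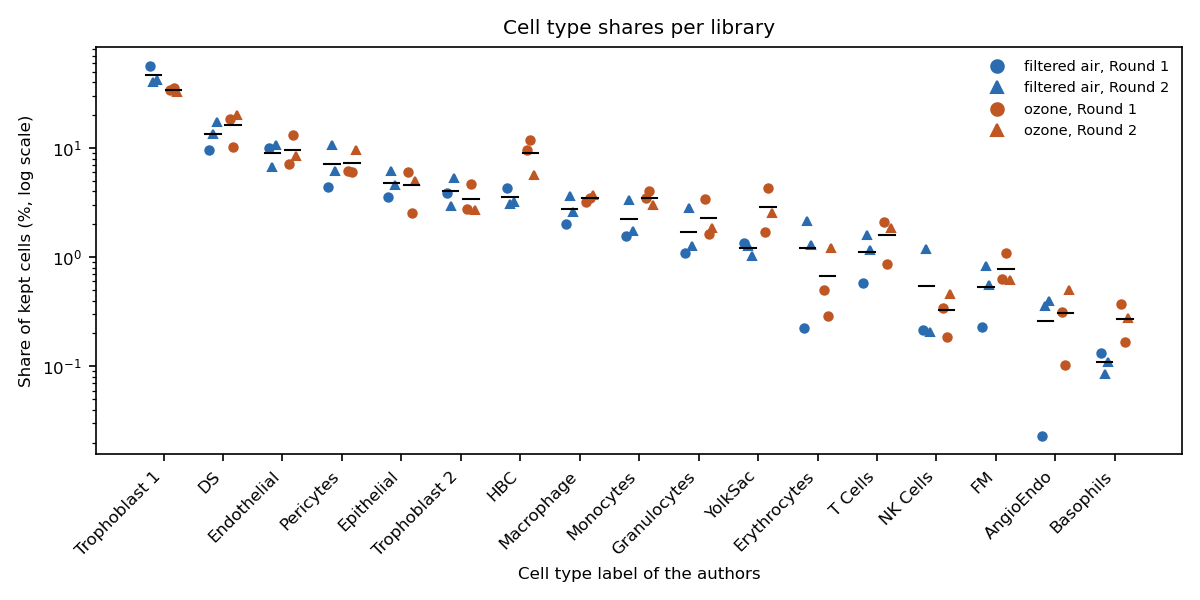
Share of kept cells, in percent on a log scale, for each cell type label of the authors, with a point per library (blue filtered air, orange ozone, circles Round 1, triangles Round 2) and a bar at the group mean of 3 libraries. The 3 ozone points of HBC, with a mean of 8.97%, lie above the 3 filtered air points, with a mean of 3.54%.

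Y-linked genes separate fetal cells of male placentas from maternal cells, and each pool of 7 placentas held some of their UMIs. Over the 6 libraries together their CPM, the UMIs scaled to a fixed total, was 75.4 in Endothelial, 66.6 in Macrophage and 52.4 in Trophoblast 1 cells. In DS and Epithelial cells the values were 2.71 and 2.57, and in HBC cells 3.74. AngioEndo cells had the lowest value, 1.97 CPM from 4 of 2028448 UMIs in 107 cells, far from the 75.4 CPM of the Endothelial label with which they are summed for the tests. HBC values per library ran from 0.99 CPM in ozone 1 to 9.70 in filtered air 2, and Macrophage values from 30.1 to 88.9. Ozone 1 was also lowest in Endothelial (43.8), Pericytes (8.77) and FM cells (19.2), but not in YolkSac cells (41.7). The X-inactive and Y-linked list passed preset-correlation camera over all cells (adjusted p 0.0271), but not without ozone 1 (0.153) or filtered air 3 (0.0934). The labels do not give the sex mix of the pools, so a difference in it cannot be told apart from exposure.

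**Figure D2:**
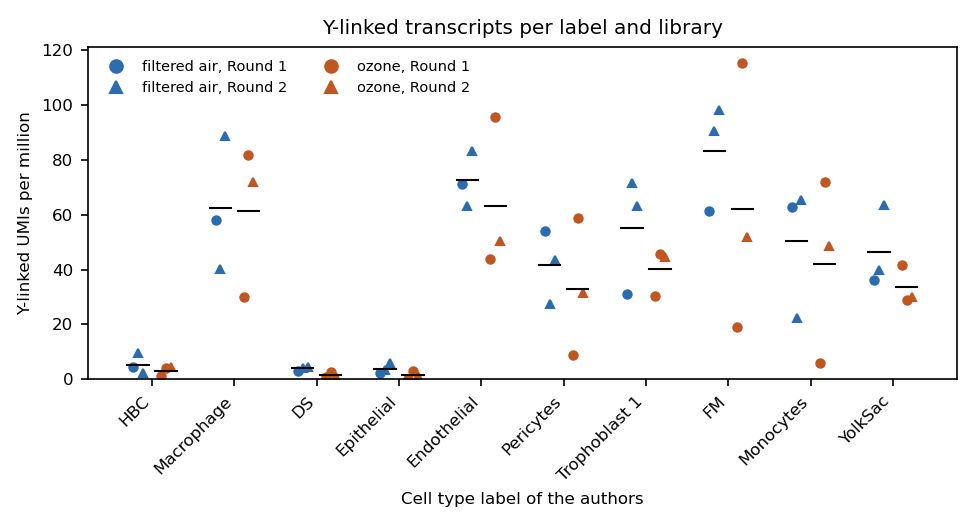
Y-linked UMIs of a cell type in CPM, for 10 cell type labels, with a point per library (blue filtered air, orange ozone, circles Round 1, triangles Round 2). HBC, DS and Epithelial cells lie lowest, with HBC at 3.74 and Macrophage at 66.6 CPM over all libraries.

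Over all kept cells, the genes with the smallest p included Wfdc18, a secreted whey acidic protein family member, at 2.87 ± 0.70 CPM in filtered air and 9.29 ± 4.32 in ozone sums (SD, n = 3 each), a log2 fold change of 1.70 (SE 0.41). Ms4a1, which encodes the B cell surface protein CD20, had a log2 fold change of 1.70 (SE 0.44), from 0.54 ± 0.07 to 1.78 ± 0.87 CPM. H2ac10, a replication-dependent histone gene, had -2.90 (SE 0.71), from 5.43 ± 4.68 to 0.76 ± 0.37 CPM. Within Round 1 and Round 2 the log2 differences were 1.72 and 0.86 for Wfdc18, 1.38 and 2.13 for Ms4a1 and -1.23 and -3.23 for H2ac10. None of these passed correction. With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 0 of 15098 genes had an adjusted p below 0.05, and 400 lay below an unadjusted p of 0.05 where chance gives 755. DESeq2 also called 0, with 741 at an unadjusted p below 0.05. The 3 ozone sums lay on one side of the 3 filtered air sums for 1287 genes, 8.52% of those tested, where chance gives 10%. The other genes of the 10 with the smallest p were Slc24a2 (log2 fold change 2.34), Hoxb9 (1.09) and Gtsf1 (1.87), higher in ozone. Lower in ozone were Zfp334 (-0.84), Slc35d3 (-2.86), Fam183b (-1.57) and Pcdhgb2 (-1.38), each with an adjusted p of 0.748. All 10 genes had the pooled direction within both rounds. This must follow where the 3 ozone sums lie on one side of the 3 filtered air sums, as for each of these genes. It is therefore no check against an effect of round. H2ac10 and Pcdhgb2 belong to families of near-identical or overlapping genes, so their counts are uncertain. In GENCODE M21 on mm10, Wfdc18 (ENSMUSG00000000983) lies on chromosome 11 from 83709015 to 83711348, Ms4a1 (ENSMUSG00000024673) on chromosome 19 from 11249675 to 11266241 and H2ac10 (ENSMUSG00000061991) on chromosome 13 from 23533906 to 23534304.

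The 61 gene lists fixed before the data were examined were compared next over all cells. Sums over all cells mix cell types whose shares differed between libraries, as HBC did with 3.54% in filtered air and 8.97% in ozone. A shift in them cannot be told apart from a change in the mix of cells. Lysosomal genes had 18 of 18 measured members at positive log2 fold changes and a median of 0.48. Among them were Psap, which encodes the precursor of the saposins (0.82), and Grn, which encodes progranulin (0.70). Immediate early genes, which respond within minutes to many stimuli, had 17 of 18 members at positive values with a median of 0.39 (Dusp1 0.69, Fos 0.56, Nr4a1 0.62). Inflammatory cytokines and chemokines had 20 of 21 with a median of 0.56 (Tnf 0.56, Ccl3 0.63). Glycolytic enzymes had 12 of 14 with 0.33 (Eno1 0.56, Ldha 0.53), and fibrillar and basement membrane collagens 12 of 15 with 0.64 (Col6a2 0.88, Col1a2 0.92). Cell cycle genes went the other way, with 20 of 20 members at negative values and a median of -0.96 (Top2a -1.04, Cdk1 -1.27, Birc5 -1.63). B cell markers were at positive values in 7 of 7 members, median 1.24. The 3 genes Ms4a1, Cd19 and Cd79a fell below 0.05 when adjusted over the list alone (smallest adjusted p 0.0396), as no member of the other lists of this paragraph did. That adjustment does not cover the 61 lists tested, and no gene passed edgeR's test over all genes. Markers of macrophages and monocytes were also higher, 12 of 12 with a median of 0.46 and an adjusted p of 0.000239 by the list test given next, or 0.670 with an estimated correlation and 0.0879 without filtered air 2. Fibroblast and stroma markers were higher along with the collagens, 10 of 10 with a median of 0.69 and an adjusted p of 0.0105, or 0.670 with an estimated correlation, 0.0552 without ozone 1 and 0.543 without ozone 3.

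The list test, limma's camera with a preset correlation between genes, put 29 of the 61 lists past an adjusted p of 0.05 over all cells, 20 higher and 9 lower in ozone. Other splits of the 6 libraries into 3 and 3 put 11 to 35 lists past it, so the number 29 is not particular to exposure. In the real split camera's adjusted p was 7.01e-09 for lysosome, 1.15e-06 for immediate early genes, 3.47e-06 for inflammatory cytokines, 7.79e-05 for glycolysis, 0.000153 for collagens, 5.26e-05 for B cell markers and 3.80e-07 for cell cycle genes. With an estimated correlation 0 of 61 passed, with an adjusted p of 0.670 for each of these 7 lists. fry, a rotation test of each list by itself, also passed 0 with an adjusted p of 0.749. These 7 lists were also the 7 that kept their call without each library in turn. Most of the shift lay in Round 2. In that round filtered air 2 stood apart from all other libraries over all cells, with Ctsq at 137 CPM against 2435 to 5148 and the embryonic hemoglobin gene Hbb-y at 3660 CPM against 104 to 2415. The mean log2 CPM of the lysosomal genes differed by 0.13 in Round 1 and 0.71 in Round 2, that of the immediate early genes by 0.08 and 0.72, that of the inflammatory genes by 0.03 and 0.92. Glycolysis differed by 0.19 and 0.34 and cell cycle genes by -0.15 and -0.85, while the collagens differed by -0.06 in Round 1 and 1.09 in Round 2. B cell markers differed by 0.50 and 1.72, macrophage markers by -0.04 and 0.92, and fibroblast and stroma markers by -0.07 and 1.27.

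Lists of responses to oxidants and to low oxygen shifted by smaller medians over all cells. The NRF2 oxidative stress list, which holds antioxidant and detoxifying enzymes, had 16 of 21 members at positive values and a median of 0.28 (Hmox1 0.55, Gstm1 0.78, but Txnrd1 -0.48), with an adjusted p of 0.0128 by camera and 0.670 with an estimated correlation. Its call was lost without filtered air 3 (adjusted p 0.242) and without ozone 1 (0.107). The hypoxia list had 16 of 20 at positive values, a median of 0.20 and an adjusted p of 0.01, or 0.670 with an estimated correlation. It lost its call without filtered air 3 (0.0606), ozone 1 (0.0531) or ozone 2 (0.0765). Ribosomal protein genes were lower in 29 of 29 members, median -0.37, and nuclear genes of oxidative phosphorylation in 25 of 25, median -0.27 (adjusted p 8.96e-06 and 0.000153, or 0.670 each with an estimated correlation). Both calls were lost without filtered air 2, with adjusted p of 0.0914 and 0.758. Within Round 1 and Round 2 the NRF2 list differed by 0.06 and 0.26, hypoxia by 0.11 and 0.12, ribosomal proteins by -0.03 and -0.48 and oxidative phosphorylation by -0.01 and -0.40.

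**Figure D3:**
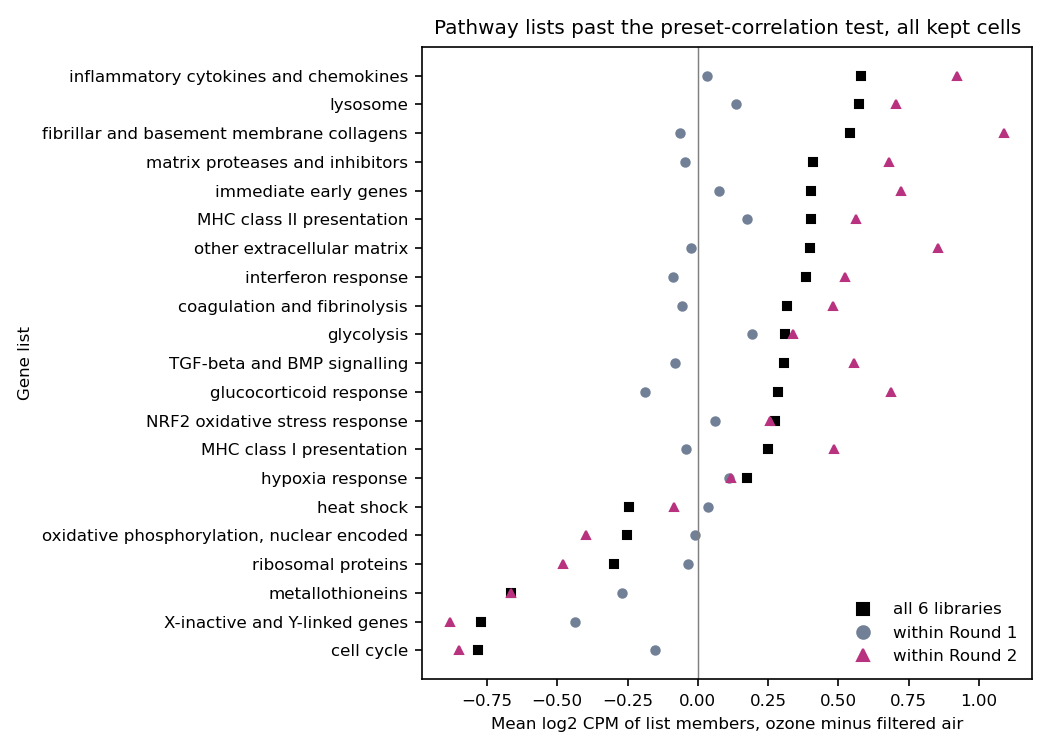
Difference in mean log2 CPM of the list members, ozone minus filtered air, for the pathway lists past the preset-correlation test over all kept cells, for all 6 libraries (black squares), within Round 1 (grey circles) and within Round 2 (magenta triangles). For each of the 21 lists the Round 1 value lies nearer 0, as for lysosome with 0.13 in Round 1 and 0.71 in Round 2.

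Endothelial cells, the sum of the labels Endothelial (4619 cells) and AngioEndo (107 cells), were compared next. Rgs5, a regulator of G-protein signalling that marks pericytes, was at 43.4 ± 15.4 CPM in filtered air and 8.68 ± 4.61 in ozone sums (SD, n = 3 each), a log2 fold change of -2.20 (SE 0.41). Scgb1a1, the secretoglobin of airway club cells and here the leading gene of the DS label, was at 90.0 ± 24.0 and 26.2 ± 7.93 CPM (-1.75, SE 0.30). The secreted Wnt antagonists Sfrp2 and Sfrp1 were higher in ozone. Sfrp2 was at 0.76 ± 0.80 against 24.0 ± 19.2 CPM (5.14, SE 1.10) and Sfrp1 at 0.59 ± 0.52 against 8.65 ± 6.84 (3.61, SE 0.93). In ozone 2 both were at 2.71 CPM. Tfrc, the transferrin receptor, was at 14.4 ± 3.26 against 6.60 ± 1.14 CPM (-1.10, SE 0.27), and Ackr3, an atypical chemokine receptor, at 13.8 ± 5.68 against 36.4 ± 11.5 (1.37, SE 0.36).

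None of these passed edgeR's quasi-likelihood test, in which 0 of 11073 genes had an adjusted p below 0.05 (each named gene 0.991) and 221 an unadjusted p below 0.05 where chance gives 554. Groups did not overlap for 807 genes, 7.29% where chance gives 10%. With the label Endothelial alone edgeR also called 0 genes, with 293 at an unadjusted p below 0.05, and DESeq2 3. In the sum of both labels DESeq2 called 3 genes, Sfrp2 at an adjusted p of 0.000685 and Scgb1a1 and Rgs5 at 0.00373 each. Within rounds the log2 differences were -2.38 and -2.22 for Rgs5, -2.08 and -1.40 for Scgb1a1, 4.06 and 4.42 for Sfrp2, and 3.99 and 2.42 for Sfrp1. The other genes of the 10 with the smallest p were Napsa (-1.18) and S100a8 (-1.21), lower in ozone, and Ttc30a1 (1.90) and Lmo7 (1.00), higher in ozone. All 10 had the pooled direction within both rounds, which must follow because the groups did not overlap for any of them. Of the pericyte markers measured in these sums, Abcc9 was also lower (-1.18) and Higd1b higher (0.79), and the list as a whole had 5 members at positive and 4 at negative values (camera adjusted p 0.555). Rgs5 (ENSMUSG00000026678) lies on chromosome 1 from 169655501 to 169695813, Scgb1a1 (ENSMUSG00000024653) on chromosome 19 from 9083636 to 9087958, Sfrp2 (ENSMUSG00000027996) on chromosome 3 from 83766321 to 83774316 and Sfrp1 (ENSMUSG00000031548) on chromosome 8 from 23411502 to 23449632.

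In endothelial cells 15 of 54 lists passed camera with the preset correlation, 5 higher and 10 lower in ozone, and 0 passed with an estimated correlation or by fry. Immediate early genes were higher in 17 of 18 members with a median log2 fold change of 0.29 (Fos 0.64, Nr4a1 0.45, Dusp1 0.35) and an adjusted p of 3.43e-05, or 0.908 with an estimated correlation. They were the only list of the 15 to keep its call without each library in turn. Ribosomal protein genes were lower in 28 of 29, median -0.28, at an adjusted p of 3.43e-05, and nuclear genes of oxidative phosphorylation in 22 of 25, median -0.34, at 0.000195, or 0.908 each with an estimated correlation. Both calls were lost without filtered air 2 (0.213 and 0.691). The inflammatory list had 15 of 21 at positive values with a median of 0.48, led by the chemokine gene Ccl7 (1.37), the adhesion molecule gene Selp (2.12) and Il6 (1.88). Its adjusted p was 0.00122, or 0.908 with an estimated correlation, 0.153 without ozone 3 and 0.162 without the cells of highest doublet scores. Cell cycle genes were at negative values in 20 of 20 members (median -0.73) with an adjusted p of 0.000195, or 0.908 with an estimated correlation, 0.0915 without filtered air 2 and 0.512 without ozone 2. With exposure in the model, edgeR also called cell cycle genes such as Ccna2 (log2 difference 2.86) and Cenpf (2.29) higher in Round 2 than in Round 1. Most filtered air libraries are of Round 2, so the pooled shift of this list is not free of round. Markers of other cells moved both ways in the same sums. Megakaryocyte and platelet markers were lower in 7 of 7 members, median -0.77, at an adjusted p of 0.00164, or 0.908 with an estimated correlation and 0.215 without filtered air 3. Macrophage and monocyte markers were higher in 6 of 8, median 0.28, at 0.0359, or 0.908 with an estimated correlation, though lower within Round 1 (-0.77) and higher within Round 2 (1.13). That call was lost without filtered air 2 (0.104), filtered air 3 (0.534) or ozone 2 (0.355), with round as a covariate (0.543) and without the cells of highest doublet scores (0.194). Other marker lists were lower, with glycogen cell markers at a median of -0.64, decidual stroma markers at -0.32 and syncytiotrophoblast I markers at -0.53 (adjusted p 0.0158, 0.0169 and 0.0169, or 0.908 each with an estimated correlation). The glycogen cell call was lost without filtered air 3 (0.215), ozone 1 (0.0663) or ozone 3 (0.173). The decidual stroma call was lost without filtered air 1 (0.25) or ozone 3 (0.153), and the syncytiotrophoblast I call without filtered air 3 (0.142) or ozone 3 (0.153). With cells of at least 2500 UMIs all 3 of these calls were lost (0.244, 0.254 and 0.103). Lists close to endothelial function did not pass, among them junctions and barrier (11 of 15 at positive values, median 0.16, adjusted p 0.117), vasoactive regulators (12 of 16, median 0.25, adjusted p 0.0730) and angiogenesis signalling (11 of 20, median 0.03, adjusted p 0.886). Within rounds the immediate early genes differed by 0.10 in Round 1 and 0.56 in Round 2, the inflammatory genes by 0.04 and 0.90 and the cell cycle genes by -0.43 and -0.21. Ribosomal proteins differed by 0.05 and -0.43 and oxidative phosphorylation by 0.03 and -0.37. Platelet markers differed by -1.13 and -0.33, glycogen cell markers by -0.52 and -0.98, decidual stroma markers by -0.39 and -0.60 and syncytiotrophoblast I markers by -0.23 and -0.87. When adjusted over the list alone, Rgs5 fell below 0.05 among the pericyte markers (adjusted p 0.00586) and Tfrc among the syncytiotrophoblast I markers (0.0189). That adjustment does not cover the 54 lists tested, and over all genes edgeR's adjusted p was 0.991 for both.

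Pericytes are taken here as the authors label them. The 10 leading genes of the label were Col1a2, Col1a1, Col3a1, Col6a1, Col6a2, Postn, Tagln, Acta2, Col5a1 and Itm2a, genes of fibroblasts and contractile cells, and none of them is in the pericyte marker list. Against the mean over all labels, fibroblast and stroma markers stood higher in this label by a mean log2 difference of 6.05, smooth muscle markers by 4.85 and pericyte markers by 3.51. Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, was at 15.9 ± 7.94 CPM in filtered air and 56.4 ± 18.1 in ozone sums (SD, n = 3 each), a log2 fold change of 1.82 (SE 0.41). Npy1r, a neuropeptide Y receptor, was at 2.95 ± 0.79 against 8.56 ± 2.51 CPM (1.53, SE 0.34), and Nlrp3, the inflammasome sensor, at 1.78 ± 0.05 against 8.36 ± 5.77 (2.17, SE 0.56). Dio2, the deiodinase that activates thyroid hormone, was at 21.5 ± 11.5 against 5.95 ± 0.65 CPM (-1.84, SE 0.38) and Tfrc at 14.8 ± 3.62 against 5.66 ± 1.41 (-1.36, SE 0.28, but -0.67 with equal numbers of cells). The neutrophil genes S100a8 (-1.88, SE 0.44) and S100a9 (-2.34, SE 0.58), the club cell secretoglobin gene Scgb1a1 (-1.19, SE 0.30) and Akr1c18, which encodes a progesterone-metabolising enzyme and is among the leading genes of the Epithelial label (-1.71, SE 0.41), were also lower in ozone. The macrophage gene Cd68 was higher (0.80, SE 0.20), with 0.42 without the cells of highest doublet scores and 1.25 with cells of at least 2500 UMIs.

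By edgeR's quasi-likelihood test 0 of 11298 genes had an adjusted p below 0.05 in pericytes (each named gene 0.936), and 280 had an unadjusted p below 0.05 where chance gives 565. DESeq2 called 0, with 340 at an unadjusted p below 0.05. Groups did not overlap for 872 genes, 7.72% where chance gives 10%. When adjusted over the list alone, Ptgs2 reached an adjusted p of 0.0452 among the inflammatory genes and Cd68 0.0281 among the macrophage markers, while Tfrc reached 0.00621 among the syncytiotrophoblast I markers and 0.0202 among the nutrient transporters. That adjustment does not cover the 54 lists tested. Within rounds the log2 differences of Ptgs2 were 2.75 and 1.46, of Dio2 -1.14 and -1.99, of Npy1r 1.16 and 1.66 and of Nlrp3 1.83 and 1.76. All 10 genes of smallest p had the pooled direction within both rounds, which must follow because the groups did not overlap for any of them. Median UMIs per pericyte were 2778 ± 2659 in filtered air and 10331 ± 3947 in ozone libraries, a difference in depth that stands beside these values. Ptgs2 (ENSMUSG00000032487) lies on chromosome 1 from 150100031 to 150108227, Dio2 (ENSMUSG00000007682) on chromosome 12 from 90724552 to 90738438, Npy1r (ENSMUSG00000036437) on chromosome 8 from 66697192 to 66706792 and Tfrc (ENSMUSG00000022797) on chromosome 16 from 32608920 to 32632794.

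**Figure D4:**
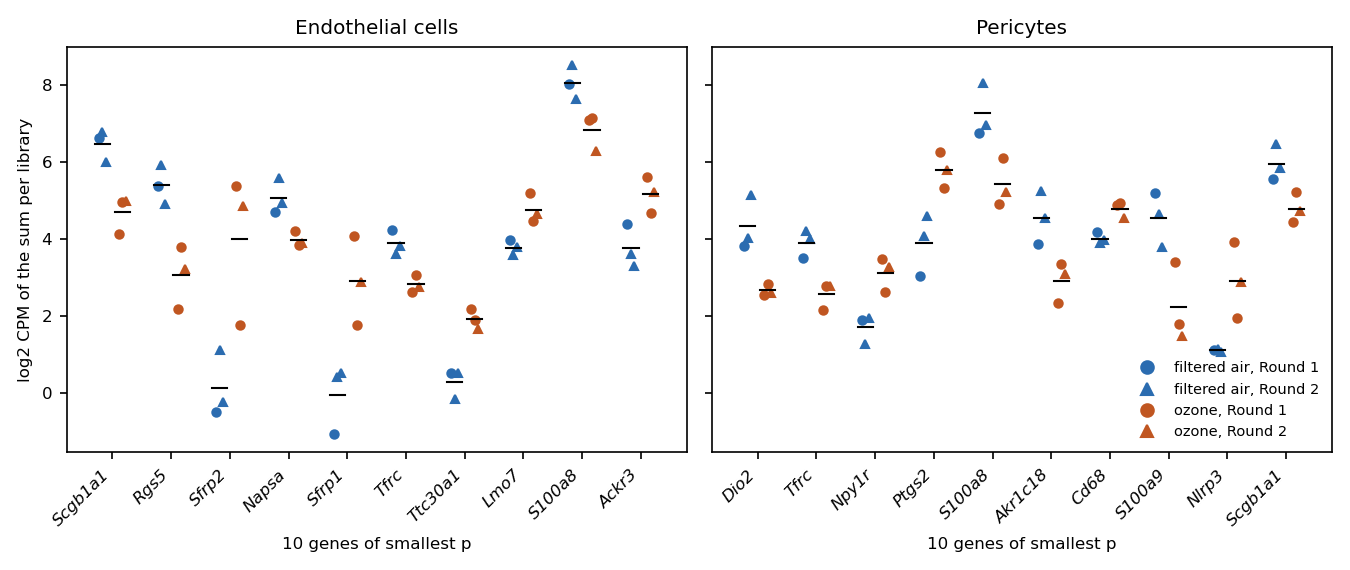
Level in log2 CPM of the 10 genes of smallest p in endothelial cells (left) and pericytes (right), with a point per library (blue filtered air, orange ozone, circles Round 1, triangles Round 2) and a bar at the group mean of 3 libraries. No gene passed the correction of edgeR's test, and for each gene the 3 ozone points lie on one side of the 3 filtered air points, as Rgs5 does with a log2 fold change of -2.20 in endothelial cells.

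In pericytes 17 of 54 lists passed camera with the preset correlation, 10 higher and 7 lower, and 0 passed with an estimated correlation or by fry. Collagens were higher in 15 of 15 members, median 0.38 (Col6a2 0.57, Col8a1 0.54, Col18a1 0.36), at an adjusted p of 4.66e-05, and immediate early genes in 16 of 18, median 0.33 (Ier3 0.56, Dusp1 0.63), at 1.33e-05. Lysosomal genes were at positive values in 15 of 18, median 0.19, at 0.00140. Fibroblast and stroma markers were higher along with the collagens, 9 of 10 with a median of 0.42, at 0.0391, or 0.628 with an estimated correlation, with differences of -0.07 within Round 1 and 0.82 within Round 2. That call was lost without filtered air 2 (0.249), ozone 1 (0.177) or ozone 3 (0.328), and with cells of at least 2500 UMIs (0.0651). The collagen, immediate early and lysosome lists each had an adjusted p of 0.628 with an estimated correlation, and they were the 3 that kept their call without each library in turn. Contractile smooth muscle genes were at positive values in 11 of 14, median 0.35 (Acta2 0.43, Lmod1 0.73), with an adjusted p of 0.0391, 0.628 with an estimated correlation, 0.0957 without filtered air 1, 0.899 without ozone 3 and 0.0687 with cells of at least 2500 UMIs. Cell cycle genes were at negative values in 18 of 20, median -0.65, at 7.60e-05, 0.628 with an estimated correlation and 0.0691 without filtered air 2. Ribosomal protein genes were lower in 29 of 29, median -0.32, at 6.97e-05, or 0.628 with an estimated correlation, and oxidative phosphorylation genes in 23 of 25, median -0.26, at 0.00234, or 0.657. Both calls were lost without filtered air 2 (0.247, and 0.471 with the direction reversed). Macrophage markers moved up in the same sums, 7 of 7 with a median of 0.78 (adjusted p 0.00228, or 0.628 with an estimated correlation and 0.0900 without filtered air 3). The placental prolactin family, which trophoblasts make and whose near-identical members share reads, was lower, 11 of 18 with a median of -0.29 and an adjusted p of 0.00128, or 0.628 with an estimated correlation. That call was lost without filtered air 3 (0.0717), ozone 1 (0.399) or ozone 3 (0.0609), and with cells of at least 2500 UMIs (0.0651). Other trophoblast lists were lower too, with syncytiotrophoblast I markers, Tfrc among them, in 3 of 4 (median -0.85, adjusted p 0.0214) and labyrinth trophoblast progenitor markers in 5 of 6 (median -0.63, adjusted p 0.0114), or 0.628 each with an estimated correlation. The former call was lost without filtered air 3 (0.0717) and with cells of at least 2500 UMIs (0.0897), the latter without filtered air 3 (0.0686) or ozone 3 (0.128) and with those cells (0.0651). Parietal and canal giant cell markers were lower in 4 of 4 (median -0.38, adjusted p 0.0460, or 0.628 with an estimated correlation). That call was lost without filtered air 1 (0.107), filtered air 3 (0.174), ozone 1 (0.285) or ozone 3 (0.448). Among vasoactive regulators Agtr2 was at 1.03 and Adm, Calcrl and Ednrb at -0.60, -1.01 and -0.66, and the list did not pass (adjusted p 0.790). Within rounds the collagens differed by -0.02 in Round 1 and 0.64 in Round 2, the immediate early genes by 0.11 and 0.65, the lysosomal genes by 0.16 and 0.33, and the cell cycle genes by 0.39 and -0.80, so that their direction was opposite in Round 1. Macrophage markers differed by 0.05 and 1.31, contractile genes by 0.02 and 0.64, the prolactin family by -0.67 and -0.96, syncytiotrophoblast I markers by -0.51 and -0.86, labyrinth progenitor markers by -0.48 and -1.16, parietal and canal giant cell markers by -0.22 and -1.25, ribosomal proteins by -0.06 and -0.48 and oxidative phosphorylation by 0.04 and -0.36.

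Whether ozone acted differently on these cells than on the rest of the placenta was tested directly, as the interaction of cell class and exposure with library as a block. By edgeR's quasi-likelihood test 0 of 14269 genes differed for endothelial cells (419 at an unadjusted p below 0.05) and 0 of 14408 for pericytes (428 at an unadjusted p below 0.05). No gene is therefore shown to respond in either class in a way that the remaining cells do not. In 2 simulated runs this test recovered 0% of 2-fold and 7.5% of 4-fold changes in endothelial cells and 0% and 11% in pericytes. Differences of these sizes were thus mostly missed there. The 2 sums of a library were simulated independently, without the dam they share in the real data, so real recovery may differ.

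In the 13 other cell types that could be tested, edgeR's quasi-likelihood test called 0 genes in total, with 36 genes at an unadjusted p below 0.05 in NK Cells and up to 575 in Trophoblast 1. DESeq2 called 20. The lowest p in HBC belonged to Timd4, a phosphatidylserine receptor of resident macrophages, with a log2 fold change of -2.77 (SE 0.54), and Fcna, a ficolin, had -2.29 (SE 0.50), both with an adjusted p of 0.891 by edgeR and of 0.00125 and 0.00130 by DESeq2. In Epithelial cells Sprr2a3, a small proline-rich protein gene, had 3.92 (SE 0.59) and Wfdc18 2.58 (SE 0.49), with an adjusted p of 0.969 each by edgeR and of 1.44e-05 and 0.000113 by DESeq2. In DS cells Arc, an immediate early gene, had 1.68 (SE 0.23) and G0s2, an inhibitor of lipolysis, -1.78 (SE 0.29), at an adjusted p of 0.971 by edgeR, and G0s2 alone passed with DESeq2 (0.00198). Without filtered air 1 edgeR's total was 168 genes, 157 of them in YolkSac cells. That library is the only filtered air one of Round 1, so without it exposure is partly confounded with round.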

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

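All tests of this part were chosen after the result was seen. Barcodes that the authors left out of their cell table are data outside the comparisons, and their share differed between the groups. They made up 15.4% ± 1.56 of barcodes in filtered air and 27.6% ± 6.53 in ozone libraries (SD, n = 3 each), a difference of 12.2 percentage points (two-sided exact permutation p = 0.1, the smallest possible). The difference was 13.8 points within Round 1 and 6.53 within Round 2. Barcodes above the mitochondrial limit took 11.8% and 16.2% (no overlap of the groups), and the other ones 3.57% ± 2.66 and 11.4% ± 5.31, for which the groups overlapped, with filtered air 1 at 6.38% and ozone 3 at 5.26% (exact permutation p = 0.2). Of the UMIs in those other barcodes, 81.2% to 93.6% per library were hemoglobin, and at most 0.155% of that was embryonic hemoglobin. No explanation of this difference was tested.

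HBC cells took a larger share of kept cells in each ozone library, 8.97% against 3.54% on average, but among cells with at least 2500 UMIs the groups overlapped (exact permutation p = 0.2), and median UMIs per HBC cell were 4406 in ozone and 2340 in filtered air libraries. The smaller within-round difference of 2.52 points exceeds the largest SD of same-group libraries within a round, 1.53. Its sign must follow, however, because the groups did not overlap, and its size rests on a round with 1 ozone library. A difference between rounds can therefore not be judged from it. Removal of other cells from the ozone libraries by the authors' filter is argued against as the whole cause. Kept HBC cells per 100 barcodes, left-out barcodes included, were higher in each ozone library, the lowest by 0.858 above the highest filtered air value. Removal of HBC cells from the filtered air libraries could not be tested, since only kept cells carry a label. Fewer Trophoblast 1 cells would by themselves raise HBC 1.23-fold against the 2.53-fold seen, and among the remaining cells the mean HBC share was 1.98 times as high in ozone, with differences of 6.24 points within Round 1 and 3.05 within Round 2. This explanation stays open, as do a difference between rounds and an effect of ozone. Among those cells filtered air 1 of Round 1, at 10.1%, overlapped ozone 3 of Round 2, at 8.40% (exact permutation p = 0.2). Within rounds the groups did not overlap, with ozone at 14.4% and 18.2% against 10.1% in Round 1. In Round 2 ozone was at 8.40% against 5.10% and 5.59%. Each round holds only 1 library of one group, too few to decide.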

How the results depend on the processing

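Of the tests here, those with the processing round as a covariate, at least 2500 UMIs, the highest doublet scores left out, the legacy fit or the label Endothelial alone were chosen after the result was seen. The count of genes stayed at 0 under all alternatives run for all cells, pericytes and both interactions. In endothelial cells DESeq2 called 3 and the other alternatives 0. Over the other cell types the total was 20 with DESeq2, 25 without a filter on low counts, 12 with the replicate block, 3 with round as a covariate, 2 with 100 cells per library and 0 to 168 without each library in turn (168 without filtered air 1). Leaving out filtered air 1 removes the only filtered air library of Round 1, so exposure is then partly confounded with round. The cause of the differing totals was not tested.

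Leaving out each library gave 17 to 34 lists over all cells, 10 to 20 in endothelial cells, 12 to 33 in pericytes and 94 to 178 in other types, against 29, 15, 17 and 128 (17 without filtered air 3, and 33 in pericytes without ozone 2). With an estimated correlation 0 lists passed in each, and with fry 0, 0, 0 and 1. With cells of at least 2500 UMIs 29 passed over all cells, 11 in endothelial cells, 10 in pericytes and 78 in other types, and with round as a covariate 32, 13 and 22 in the first 3. The replicate block gave 31, 16, 22 and 159 lists. The replicate numbers do not pair the samples: correlations of same-numbered libraries ran from -0.158 to 0.306 over all cells. The cause of these changes was not tested. The oxidative phosphorylation list in pericytes was reversed without filtered air 2 (adjusted p 0.471). Its adjusted p ranged from 5.74e-05 to 0.760 over the alternatives and from 5.74e-05 to 0.471 without each library in turn.

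The Endothelial share difference was reversed without filtered air 2 (-0.682 points) and ozone 2 (-1.26), in a range of -1.26 to 1.68. The Pericytes difference was reversed without filtered air 1 (-1.20), filtered air 3 (-0.312) and ozone 3 (-1.02), in a range of -1.20 to 1.95. Of 510 values of the 30 named genes under alternatives, 507 kept direction and side of the threshold, 3 passed with DESeq2 and 0 reversed. In pericytes the log2 fold change of Tfrc ranged from -1.54 to -0.67 and that of Cd68 from 0.42 to 1.25, and no other named gene moved by over 1.5 times.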

Other observations

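The tests of the Y-linked genes, of the source cells and of shallow cells, and the counts of splits for all cells, endothelial cells, pericytes and the interactions, were chosen after the result was seen. The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real and highest other counts of genes were 0 and 0 for all cells, 0 and 162 for endothelial cells, 0 and 41 for pericytes, 0 and 93 for the other types, and 0 and 4 and 0 and 10 for the interactions of endothelial cells and pericytes, so that 10 of 10 splits gave at least the real count. The values 162, 41, 93, 4 and 10 all came from the split that follows the processing rounds, which points to a structure of the samples by round. With exposure in the model, edgeR called 34 genes for round in endothelial cells, 6 in pericytes and 1 over all cells. For lists, the real and highest other counts were 29 and 35 over all cells (2 splits as large), 15 and 24 in endothelial cells (5), 17 and 27 in pericytes (4) and 113 and 212 in the 11 other types with all 6 libraries (9).

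Y-linked UMIs in HBC cells lay far below those in Macrophage cells. A lack of male placentas is argued against, since the lowest Macrophage value among the libraries was 30.1 CPM. A candidate explanation is that HBC cells were mostly of maternal origin: the ratio of HBC to Macrophage values was at most 0.242. That highest ratio, in filtered air 2, lies close to the bound of 0.25, which was itself set after the pooled values were seen.

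Scgb1a1 and S100a8 were lower in ozone in endothelial cells and pericytes, cells that are not the main source of either. Scgb1a1 was also lower in HBC cells (log2 fold change -1.66) and S100a8 in Epithelial (-1.39) and T Cells (-1.46), of which DESeq2 called the first and second (adjusted p 0.0157 and 0.0105) and edgeR none. Lower levels were not seen in the cells taken as sources: Scgb1a1 in DS cells and S100a8 in Granulocytes had log2 fold changes of 0.24 (SE 0.46) and 0.72 (SE 0.75). With SEs of this size a fall is not excluded. Whether other cells, such as Epithelial ones, also supplied S100a8 was not tested. Shallow cells in filtered air libraries are argued against, as the median of the 4 log2 fold changes was -1.69 with cells of at least 2500 UMIs and -1.48 with all. RNA from other cells may have made a smaller part of the ozone sums, but this stays open: leading genes of 6 of 7 other labels had a lower ratio of class to all-cell CPM in endothelial cells, and of 5 of 7 in pericytes, but those of DS, the source of Scgb1a1, were higher in both (mean log2 differences of 0.03 and 0.19).

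In HBC cells 16 of 53 lists passed camera with the preset correlation and 10 of these were kept without each library in turn. YolkSac cells had 17 of 40, and Trophoblast 1 cells 18 of 58. With an estimated correlation 0 passed in any of these types. The Trophoblast 2 label is led by platelet genes such as Gp9, Ppbp and Pf4, and AngioEndo by genes of lymphatic vessels such as Prox1, Lyve1 and Flt4.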
